A study of Drosophila melanogaster with 2 samples.

How the data were processed

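The samples were whole Drosophila melanogaster embryos of 0 to 24 hours that expressed CG32767 fused to eGFP, immunoprecipitated with an antibody against GFP, in 2 biological replicates with 1 library each. Per the labels, chromatin was sheared by sonication with a stated size range of 200 to 800, without a unit. The labels point to a general protocol and a possible control experiment, and neither was analysed here. The aligner, the peak caller, the handling of the control and any list of excluded regions are not given in the sources used here. The assembly was dm6, per the labels.

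The authors deposited 8 peak lists, of which 4 were thresholded and 4 ranked all candidates. Each kind was given for replicate 1, for replicate 2, and in 2 versions for both replicates combined. Lists were filtered by the irreproducible discovery rate (IDR), a rate estimated from how well peak ranks agree between 2 sets of peaks. The sources do not state what was compared within a single replicate. The signal of each peak, in the units of the authors' peak caller, was used as deposited, to rank and describe peaks within a list. The score in the deposited thresholded lists is a scaled IDR, and its minimum of 830 in each of these 4 lists corresponds to an IDR of 0.01. The −log10 of the global IDR, in the deposited ranked lists, was used to count candidates. In the ranked list behind the conservative one 3658 candidates had an IDR of at most 0.01, more than the 3533 peaks of the conservative list, and the filter that removed the rest is not given in the sources used here. The planned stricter IDR of 0.01 would have removed no peak, so the fallback fixed with it was used, the upper 50% of the main list by signal. Most peaks had 1 fixed width per list, 390 bp in 82.1% of conservative peaks. The deposited lists give no read counts, so the depth of each library is unknown, and the intervals below cover counting error over peaks, genes or windows alone.

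The conservative list of the whole series was the main list. Files were read in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Genes and TSSs came from Ensembl release 115 (BDGP6.54), and sequence from the RefSeq dm6 assembly. Chromosome lengths held every peak of the lists, and 17670 of 17672 genes with the same symbol in the Ensembl and RefSeq annotations had identical coordinates. On the 6 arms there were 18164 genes other than transposable elements, 13945 of them protein-coding, and 23581 distinct TSSs. Positions are 1-based. Peaks on other scaffolds were left out of tests that need the annotation.

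Replicate lists were compared by overlap of at least 1 bp against 100 random placements. The signal of a named peak in a replicate is that of the strongest overlapping candidate in that replicate's own ranked list. Each summit was assigned to the first class that applied among promoter (within 500 bp of a TSS), 5' untranslated region, coding exon, 3' untranslated region, non-coding exon, intron and intergenic, and the counts were set against 1000 random placements on sequenced bases of the same chromosome. Densities have exact Poisson intervals, and the X was compared with the autosome arms by an exact binomial test on lengths. Shares have 95% exact Clopper-Pearson intervals.

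Of 34 gene lists fixed before the data were examined, 33 were tested, since the annotation used held no gene of the microRNA class. Of 406 symbols in these lists, 10 were not matched in the annotation, and their genes are not reported here. Protein-coding lists were compared with all other protein-coding genes and RNA gene lists with all other genes, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment at 0.05. The 28 motifs were searched on both strands in windows that reached 50 bp to either side of summits and in windows centred 500 bp to either side. Words of 7 letters were ranked on summits of odd signal rank, and the top 10 tested on those of even rank. Median log2 signals of promoter and other summits were compared by a permutation test with 100000 resamples across peaks, which are not replicates. Intervals for base composition come from 10000 bootstrap resamples of windows.

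Genes were named by a rule fixed before the data were examined. It took the gene with the TSS nearest to each of the 20 strongest main-list peaks, and the 5 strongest peaks over 2 kb from any TSS. It also took the 4 members with the strongest promoter peak of each list past the threshold, 2 members of each other patterning or tissue list where it had any, and CG32767. Other genes named among the closing observations were chosen after their values were seen.

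The placement, gene list, motif, word and median signal tests were tried on simulated data, and the other tests were not. The random placement test found a planted shift of summits to promoters in 20 of 20 simulations of 3531 summits, and called 2 of 20 without one. The gene list test found the planted list in 20 of 20 simulations over 13945 genes, with 1 call in 560 tests of other lists. The motif test found the planted motif in 20 of 20, with 2 calls in 540 tests of the others, and the word search found the planted word in 20 of 20. The median test found a planted shift in 19 of 20 and called 2 of 20 without one.

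Alternatives were the other series-level list, the upper 50% of the main list by signal, the list of either replicate alone, TSS windows of 250 and 1000 bp, protein-coding TSSs alone, peak middles in place of summits, other backgrounds for genes and motifs, windows of 51 and 201 bp, words of 6 and 8 letters, a distance of 50 kb around CG32767, and stricter overlap. An alternative that keeps the strongest of summits within 1000 bp of each other was added after seeing the data.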

Results

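Binding of the Drosophila melanogaster protein CG32767 was mapped by chromatin immunoprecipitation and sequencing in whole embryos collected 0 to 24 hours after laying. The flies carried a transgene for CG32767 fused to enhanced green fluorescent protein (eGFP), and the fusion was precipitated with an antibody against GFP. There was 1 group of 2 biological replicates, so the values below describe where the tagged protein was found and how far the replicates resembled each other. No control library was analysed here. The lists give no read counts, so the depth of each library is unknown. The authors' conservative list, made from both replicates, held 3533 peaks in 3274 separate regions that together covered 1217832 bp of the dm6 genome. It is called the main list below, and 3531 of its peaks lay on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X. Peak signal is the authors' value in the peak caller's own units, and it ranks peaks within 1 list only.

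The strongest sites lay mostly at promoters of protein-coding genes. Of the 20 strongest main-list peaks, 16 had a summit within 500 bp of a transcription start site (TSS), and 17 had a protein-coding gene as the nearest. The signals of these 20 ran from 845.2 to 1304, and each was also in the list of either replicate. The highest, 1304, lay in an intron of CG11050 on 2L (6612523 to 6612898), 1026 bp downstream of its TSS, with signals of 749.5 in replicate 1 and 546.4 in replicate 2. The next, 1302, lay within the overlapping spans of vig, vas and solo, 42 bp upstream of a vig TSS (2L, 15067913 to 15068304), with 568.0 in replicate 1 and 726.0 in replicate 2. A peak of 1250 lay inside the span of ph-p, 474 bp upstream of an internal TSS of this gene, which encodes the Polycomb group protein Polyhomeotic (X, 2136809 to 2137756), with 745.0 and 451.0 in replicates 1 and 2. Ugalt, a UDP-galactose transporter gene, had a peak of 1188 (X, 2703733 to 2704048) and Cirl, which encodes a latrophilin receptor, a peak of 1137 (2R, 8614483 to 8614934), with summits 46 and 43 bp upstream. Genes of the mitochondrial ribosome recurred, with mRpL41 at 1104 (2R, 15217606 to 15217903), mRpS10 at 959.6 (3R, 15229377 to 15229698) and mRpS23 at the promoter it shares with CenG1A, 867.0 (2L, 13835314 to 13835617). Other genes nearest to the 20 were CG14100 (1091), PNPase (1013), HmgZ (975.9), Ggamma1 (972.7), Chro (913.1), Fkbp14 (892.8), CG5611 (859.9) and CG18549 (845.2). HmgZ encodes a high mobility group protein, and Chro the chromatin protein Chromator. The remaining ones were near the non-coding RNA genes lncRNA:CR44619 (1073), lncRNA:CR44339 (897.5) and lncRNA:CR45643 (874.1), and between genes on 2R (13035177 to 13035494), where the signal was 1014 and the nearest TSS, that of CG13323, was 11914 bp away.

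Some sites lay far from any TSS. Of the 3531 summits, 948 (26.8%, 95% exact interval 25.4 to 28.3) lay over 2000 bp from any TSS. After the intergenic site on 2R, the strongest of these lay in introns of Tlk, the Tousled-like kinase gene (705.4, X, 3742075 to 3742358), and CG12769 (687.9, 2R, 8060870 to 8061170). The others were an intergenic site 3764 bp from the TSS of CG31668 (634.4, 2L, 2202257 to 2202546) and an intron of CG32486 (556.6, 3L, 3060676 to 3060937).

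The first comparison was between the replicates. The list of replicate 1 held 2887 peaks, of which 1653 (57.3%, 95% exact interval 55.4 to 59.1) overlapped a peak of replicate 2 by at least 1 bp. The list of replicate 2 held 2624 peaks, of which 1693 (64.5%, 62.7 to 66.4) overlapped a peak of replicate 1. When 1 list was placed at random within its chromosomes 100 times, the overlaps averaged 1.28% and 1.49% and never exceeded 2.32%. Across the 1653 shared peaks, log2 signals had a Pearson correlation of 0.55 and a Spearman correlation of 0.61. Across the 1494 with summits within 100 bp of each other, these were 0.72 and 0.67. Peaks are not independent replicates, so no p-value is given. Most peaks of 1 list alone overlapped a candidate of any signal in the other replicate's ranked list. These were 1175 of the 1234 peaks of replicate 1 alone and 804 of the 931 of replicate 2 alone. The overlapped candidates had a median rank percentile of 93.9 in replicate 2 and 94.2 in replicate 1. The ranked lists cover 29740659 bp in replicate 1 and 27552423 bp in replicate 2, and the overlap at random positions was not computed. Among the named genes, piwi, which encodes a germline Argonaute protein, had signals of 127.9 in replicate 1 and 32.5 in replicate 2 and a peak in the first list alone. The fourth-chromosome gene ci, the transcription factor of Hedgehog signalling, had signals of 29.7 and 78.8 and a peak in the second list alone.

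**Figure D1:**
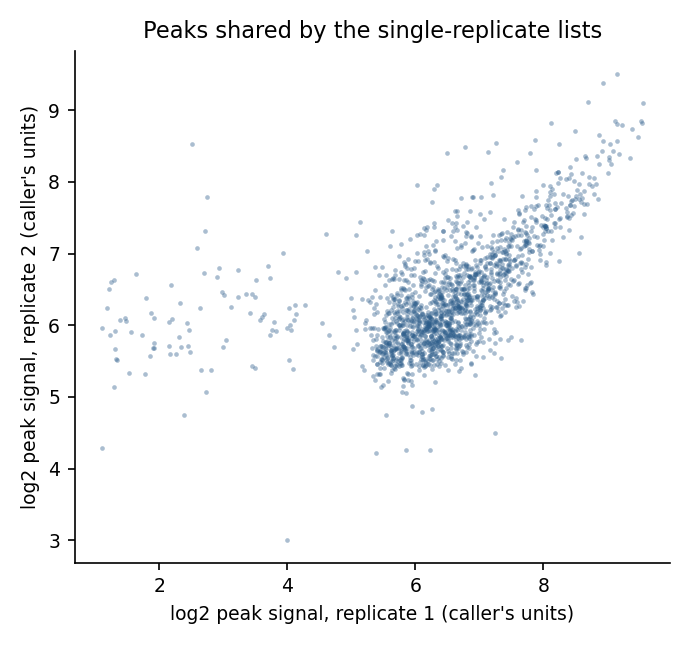
Each point is 1 of the 1653 peaks of replicate 1 that overlap a peak of replicate 2, with log2 peak signal in the caller's own units for replicate 1 on the horizontal axis and for the strongest overlapping peak of replicate 2 on the vertical axis. The strongest replicate 1 peaks scatter around a rising trend, some of them well above it. Some of the strong replicate 2 peaks overlap replicate 1 peaks of much lower signal. A cluster of low values on the left holds weak replicate 1 peaks that overlap stronger replicate 2 peaks. Many of these replicate 2 peaks also overlap a stronger replicate 1 peak and are drawn again with it. An example is the replicate 2 value of 8.53, paired with 8.25 and with 2.51, so the cluster does not by itself show sites weak in replicate 1.

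The conservative list was nearly contained in the authors' other list for the whole series. Of its 3533 peaks, 3305 (93.5%, 95% exact interval 92.7 to 94.3) overlapped that longer list of 4636 peaks, and 1293 of the 4636 overlapped no conservative peak. The additional peaks were weaker, with a median signal of 65.1 against 108.3 for those in both. Of the conservative peaks, 1617 (45.8%) were in both single-replicate lists and 691 (19.6%) in neither. Among the 217 peaks with a signal under 40, 205 had a stronger summit within 1000 bp.

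CG32767 was found at promoters far more often than by chance. Of the 3531 summits, 1788 (50.6%, 95% exact interval 49.0 to 52.3) lay within 500 bp of a TSS, against 13.6% ± 0.573 (SD) in 1000 random placements within the same chromosomes. The difference had a permutation p of 0.002, two-sided, the smallest that 1000 placements can give. Promoter summits sat upstream of the nearest TSS in 1260 of 1788 cases (70.5%, 68.3 to 72.6), with a median position of -91.5 bp. Of the 13945 protein-coding genes on the arms, 1965 (14.1%, 13.5 to 14.7) had a summit within 500 bp of a TSS.

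Coding exons and 3' untranslated regions were almost free of summits. Coding exons held 18 summits (0.510%) against 13.7% at random, and 3' untranslated regions held 26 (0.736%) against 4.40%. Introns held 1231 summits (34.9%), close to the 39.4% of the random placements but below it, and intergenic sequence held 412 (11.7%) against 27.3%. These 4 classes and promoters had an adjusted permutation p of 0.0028 over the 7 classes. The 5' untranslated regions, with 22 summits (permutation p = 0.338), and non-coding exons, with 34 (permutation p = 0.312), did not pass the test. Sequence counted as promoter was not counted again in these classes, so exons within 500 bp of a TSS are left out of them.

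**Figure D2:**
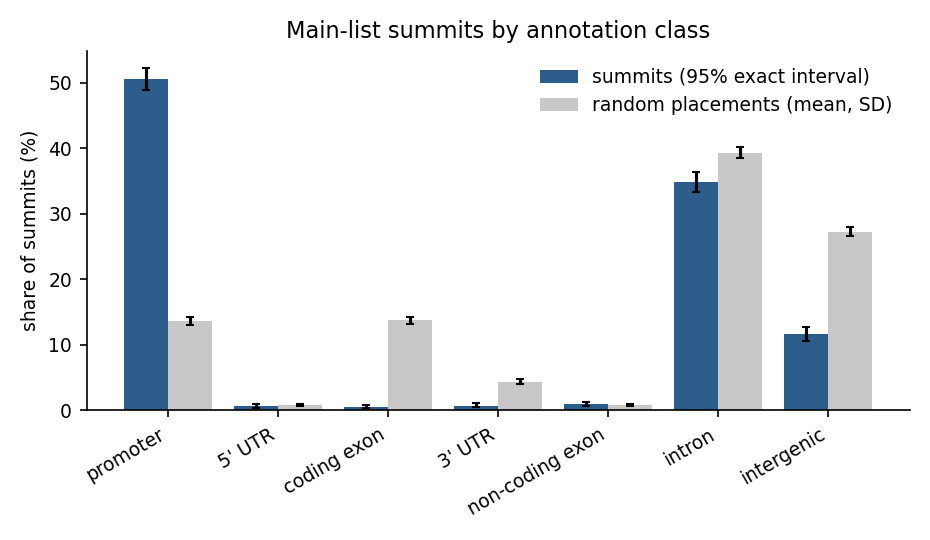
Bars give the share of the 3531 main-list summits in each annotation class in percent, with 95% exact intervals, beside the mean and SD of 1000 random placements within the same chromosomes. Promoters hold 50.6% of summits against 13.6% at random, and coding exons 0.510% against 13.7%.

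In the main list the major autosome arms and the X were bound at similar densities and the fourth chromosome less densely, but the replicates differed on the fourth. There were 28.0 summits per Mb on 2L (95% exact Poisson interval 25.9 to 30.2), 27.4 on 2R (25.4 to 29.5), 27.4 on 3L (25.5 to 29.4), 24.9 on 3R (23.2 to 26.7) and 25.7 on the X (23.7 to 27.9). The fourth chromosome, a small and largely heterochromatic chromosome, had 10 summits, or 7.51 per Mb (3.6 to 13.8). In the list of replicate 1 it had 7 summits, or 5.26 per Mb (2.11 to 10.8), and in that of replicate 2 it had 35, or 26.3 per Mb (18.3 to 36.6), the highest density of that list. The density on the X was 0.960 times that on the autosome arms (0.878 to 1.05), which an exact binomial test on their lengths did not separate from 1 (p = 0.378). In the list of replicate 2 alone the ratio was 0.837 (exact binomial p = 0.000988), and in that of replicate 1 it was 1.01 (exact binomial p = 0.845). These tests expect summits in proportion to length. Distinct TSSs were themselves 0.929 times as dense on the X as on the autosomes (0.898 to 0.962), which the tests do not allow for.

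Among 33 gene lists fixed before the data were examined, ribosomal protein genes and 4 lists of regulatory genes had promoter summits more often than other protein-coding genes. Of 85 genes of the cytoplasmic ribosome, 43 (50.6%, 95% exact interval 39.5 to 61.6) had a summit within 500 bp of a TSS, against 13.9% of the other genes (odds ratio 6.36, adjusted p = 2.107e-14, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists). The strongest in the group were RpL34b (195.3), RpL32 (182.7), RpS20 (168.4) and RpS27 (154.3), of modest signal beside the peaks named above. Each of these summits also lay within 500 bp of another gene's TSS, of CG8132, CG7943, CG17271 and Nup37 in that order. Of 73 genes of the mitochondrial ribosome, 19 (26.0%, 16.5 to 37.6) had one (odds ratio 2.16, adjusted Fisher's exact p = 0.0207), led by mRpL41 (1104), mRpS10 (959.6), mRpS23 (867.0) and mRpL23 (666.3). The summits named for the mitochondrial ribosome were shared in the same way, with lncRNA:CR44463, Art3, CenG1A and CG9004. The cytoplasmic list passed under 9 of 10 alternatives and the mitochondrial list under 3.

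Of 12 genes for zygotic genome activators and pioneer factors, 8 (66.7%, 34.9 to 90.1) had a promoter summit (odds ratio 12.2, adjusted Fisher's exact p = 0.000246). The strongest were Clamp (246.7), whose product binds GA repeats, Trl (152.5), which encodes GAGA factor, phol (147.4) and Dref (139.6), which encodes the factor that binds the DNA replication-related element. Insulator and architectural protein genes had 8 of 18 (44.4%, 21.5 to 69.2, odds ratio 4.89, adjusted Fisher's exact p = 0.00657), led by Chro (913.1) and Cp190 (350.2), with Trl and pita (149.9) after them. Polycomb and Trithorax group genes had 9 of 29 (31.0%, 15.3 to 50.8, odds ratio 2.75, adjusted Fisher's exact p = 0.0417), led by the neighbouring ph-p (1250) and ph-d (687.7), then brm (538.2), an ATPase of chromatin remodelling, and E(z) (311.9), the histone H3 methyltransferase of Polycomb repressive complex 2. Trl counts among both the activator and the insulator genes, and phol among both the activator and the Polycomb and Trithorax group genes. The summit at Dref also lay within 500 bp of the TSS of RpL13 and counts for the cytoplasmic ribosome as well. Other genes likewise had a TSS within 500 bp of the summits at phol (CG3552), Chro (Ssl1), Cp190 (CG4338) and pita (Dcp-1). The same held for brm (Arl1) and E(z) (Cnep1r2), but not for Clamp, Trl, ph-p or ph-d. The activator list passed under 9 of 10 alternatives, the insulator list under 7 and the Polycomb and Trithorax list under 5.

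With the main list, segment polarity genes were the 1 patterning list that passed, with 6 of 15 (40%, 16.3 to 67.7, odds ratio 4.07, adjusted Fisher's exact p = 0.0373). They were led by arm, the fly beta-catenin (280.3), nkd (201.6), ptc (134.9) and ci (108.2). They passed under 3 of 10 alternatives. The other patterning and tissue lists did not pass with the main list. With the other series-level list neurogenesis genes (10 of 27, adjusted Fisher's exact p = 0.0364), mesoderm and muscle genes (11 of 27, 0.0121) and trachea genes (6 of 12, 0.0249) were higher. In the list of replicate 2 neurogenesis genes (7 of 27, adjusted Fisher's exact p = 0.0495) and mesoderm and muscle genes (8 of 27, 0.0202) were higher as well. Hox genes had 1 of 8 (Abd-B, 344.6), pair-rule genes 1 of 9 (odd, 49.9), dorsoventral genes 1 of 19 (cact, 197.8) and hemocyte and fat body genes 1 of 18 (ush, 104.7). Maternal and gap genes had 3 of 14, with bcd (137.2) and ems (117.8) the strongest, and germline genes 2 of 13, piwi (158.6) and bgcn (98.1). Neurogenesis genes had 7 of 27, led by elav (620.8) and numb (299.9), and mesoderm and muscle genes 7 of 27, led by tin (356.6) and Msp300 (261.2). Endoderm and gut genes had 2 of 12, fkh (199.9) and grn (131.7), and trachea genes 4 of 12, led by trh (129.1) and bnl (115.9).

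Chemosensory receptor and cuticle protein genes lacked promoter summits. None of the 179 chemosensory receptor genes had a summit, which allows at most 2.04% (adjusted Fisher's exact p = 2.331e-11), and none of the 114 cuticle protein genes, which allows at most 3.18% (adjusted Fisher's exact p = 3.417e-07). The repeated replication-dependent histone genes had 0 of 111 (adjusted Fisher's exact p = 4.211e-07), but 1 of the 111 had any candidate peak in the ranked list, so that count says little about them. Among RNA genes, 16 of 290 tRNA genes (5.52% against 12%, adjusted Fisher's exact p = 0.00136), 14 of 269 snoRNA genes (5.20% against 12%, adjusted Fisher's exact p = 0.00131) and 165 of 3261 long non-coding RNA genes (5.06% against 13.4%, adjusted Fisher's exact p = 2.762e-46) had one. With summits anywhere in the gene or 2 kb upstream snoRNA genes were higher instead (75 of 269, odds ratio 1.60, adjusted Fisher's exact p = 0.0031). Some of the promoter summits of RNA genes also lay within 500 bp of another gene's TSS, as for tRNA:Tyr-GTA-1-8 with CG8036 (374.8) and lncRNA:CR44463 with mRpL41 (1104). The tRNA genes tRNA:Trp-CCA-2-2 and tRNA:Gly-GCC-1-9 shared 1 peak (156.3), tRNA:Val-CAC-2-5 had one at Naam (124.3), and snoRNA:Or-aca5 and snoRNA:Psi28S-2949 shared one at Uhg4 (189.6). Further members were snoRNA:Or-ACA6 (142.5), snoRNA:U49:66Da (130.6) and lncRNA:enrr (620.8), which shares the summit upstream of elav.

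With the main list, lists that did not pass in either direction included signalling pathway genes (10 of 34, adjusted Fisher's exact p = 0.0547), heat shock protein genes (5 of 21), cell cycle and replication genes (7 of 37), translation initiation and elongation factor genes (10 of 51) and nuclear-encoded respiratory chain genes (10 of 76). The same held for proteasome genes (3 of 44), ecdysone pathway genes (1 of 22), immune response genes (1 of 24), yolk and chorion genes (1 of 18), snRNA genes (2 of 32) and the Jonah and trypsin protease genes (0 of 25, which allows at most 13.7%). With the other series-level list signalling pathway genes (15 of 34, adjusted Fisher's exact p = 0.000948), heat shock protein genes (8 of 21, 0.0365) and translation factor genes (16 of 51, 0.0326) were higher and the protease genes (0 of 25, 0.0326) lower. Signalling pathway genes were higher under 4 of 10 alternatives. With genes left out that have another gene's TSS within 1000 bp, 18 cytoplasmic ribosomal protein genes remained, 5 of them with a summit (27.8% against 8.10%, adjusted Fisher's exact p = 0.0816), and of the higher lists the Polycomb and Trithorax list alone passed, with fewer genes tested in each. Without replicate 2 the segment polarity, Polycomb and Trithorax and mitochondrial ribosome lists did not pass (adjusted Fisher's exact p = 0.683, 0.195 and 0.194), and without replicate 1 the insulator list did not (0.0721).

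**Figure D3:**
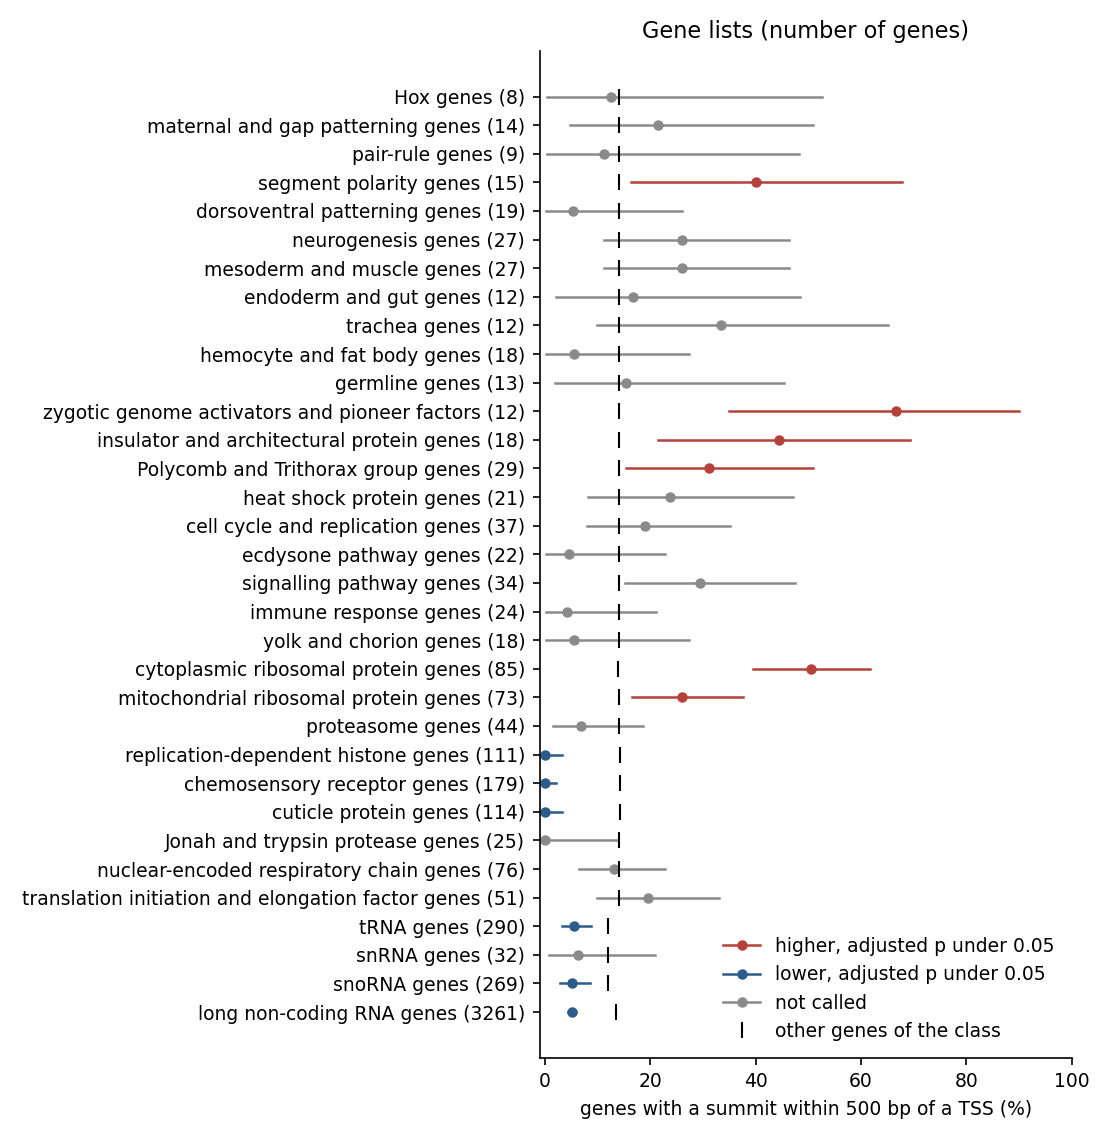
Points give the percent of genes in each of 33 lists, with the number of genes in parentheses, that had a main-list summit within 500 bp of a TSS, lines give 95% exact intervals and black ticks the percent among other genes of the class. The lists of cytoplasmic ribosomal proteins (50.6%) and of zygotic genome activators (66.7%) lie far to the right of the ticks, and chemosensory receptor and cuticle protein genes lie at 0.

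Sequence under the summits was rich in A and T. In windows that reached 50 bp to either side of the summits, G and C made up 36.3% ± 11.3 (SD, 3531 windows), against 42.3% ± 10.6 in the flanking windows 500 bp away, a difference of -6.00 percentage points (95% bootstrap interval -6.45 to -5.56). The dip was deepest at strong peaks. The 500 strongest summits had 31.0% G and C against 42.8% in their flanks, and over 4 equal parts of the list from strongest to weakest the means were 31.8%, 34.7%, 37.4% and 41.2%. It was larger in replicate 1 (33.9% at summits, 43.0% in flanks) than in replicate 2 (38.2% and 41.6%).

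**Figure D4:**
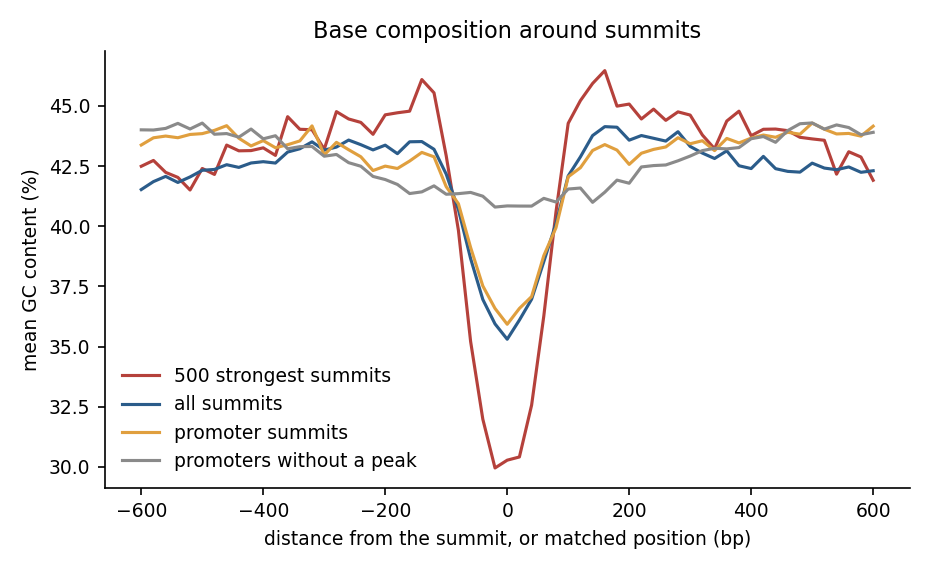
Lines give the mean G and C content in percent by distance from the summit in bp, for the 500 strongest summits, all 3531 summits, the 1788 promoter summits, and promoters of genes without a peak taken at the same distances from their TSS. The 500 strongest summits fall to 30.3% at the centre, and promoters without a peak stay at 40.8%.

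A search for 7-letter words on every other summit returned 10 words made of A and T alone, and all 10 were more frequent at the held-out summits than in their flanks. AAAATAT was in 15% of 1765 held-out windows against 7.37% of flanks (odds ratio 2.22, adjusted Fisher's exact p = 1.482e-16), and ATATTAA in 8.84% against 3.85% (odds ratio 2.42, adjusted Fisher's exact p = 1.008e-12). The odds ratios of the 10 ran from 1.70 to 2.42. Summits were richer in A and T than their flanks, and no background matched on base composition was run for words. The search therefore does not separate particular words from the AT-rich sequence described above. With replicate 2's list alone, 9 of its 10 words passed and 6 were of A and T alone.

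Of 28 motifs fixed before the data were examined, 8 were more frequent at summits than in flanks and 5 less. The DNA replication-related element TATCGATA, which Dref binds, was in 1.42% of windows (95% exact interval 1.05 to 1.86) against 0.467% (odds ratio 3.06, adjusted Fisher's exact p = 7.145e-06). Promoter summits did not differ in it from promoters of genes without a peak past the threshold (2.68% against 1.79%, adjusted Fisher's exact p = 0.104). The core of the Su(Hw) insulator protein's site was in 0.821% against 0.326% (odds ratio 2.53, adjusted Fisher's exact p = 0.00308). Core promoter motifs 1 (0.736% against 0.283%) and 6 (4.05% against 2.78%), the TATA box (2.29% against 1.33%), GATA sites (20.4% against 16.9%), homeodomain sites (8.89% against 6.5%) and A tracts (8.16% against 6.50%) were also higher. The E-box CAGGTG, a site of repressors such as Snail, was lower (1.64% against 4.01%, odds ratio 0.40, adjusted Fisher's exact p = 3.054e-10), as were the E-box CAGCTG (3.77% against 4.79%), AP-1 sites (0.566% against 1.03%), Mad sites (0.878% against 1.71%) and the CG-rich Sp/KLF box (2.75% against 4.01%). Of these calls, 11 were kept in the list of replicate 1 and 5 in that of replicate 2. Among those lost in the latter were core promoter motif 1 (adjusted Fisher's exact p = 0.0902), the Su(Hw) core (0.0738), GATA sites (0.0833), homeodomain sites (0.0968) and the E-box CAGCTG (0.789). Against shuffled windows of the same dinucleotide content, the odds ratios of the TATA box (0.836), GATA sites (0.845) and homeodomain sites (0.800) turned below 1. Those of the E-box CAGCTG (2.19, adjusted Fisher's exact p = 5.722e-09), the Sp/KLF box (1.62, 0.00143) and Mad sites (1.64, 0.0653) turned above 1. The repeats GAGAGAG, CACACACA and GTGTGTG did not pass in the main list but had odds ratios of 1.41, 1.56 and 1.52 in the list of replicate 2 and 0.583, 0.610 and 0.652 in that of replicate 1, each past the threshold. At main-list promoter summits against promoters without a peak they were higher, at 1.72, 2.98 and 2.54 (adjusted Fisher's exact p = 0.0325, 7.198e-09 and 1.294e-09), and against shuffled windows at 4.13, 4.77 and 3.36.

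Promoter peaks were slightly stronger than the rest. The 1788 promoter summits had a median signal of 111.2 and the 1743 others 99.7, a difference of 0.16 on the log2 scale (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give). The strongest of 4 equal parts of the list had 525 of 882 summits at promoters (59.5%, 95% exact interval 56.2 to 62.8) and the weakest 423 of 883 (47.9%, 44.6 to 51.3). The parts between them had 49.6% and 45.5%, so the share did not fall steadily with signal. In the list of replicate 2 the difference was 0.030 (permutation p = 0.255), and in that of replicate 1 it was 0.22 (permutation p = 1e-05).

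The gene of the tagged protein was itself among the strong sites. CG32767 (FBgn0052767) spans 5071027 to 5084768 on the X, on the minus strand. The main list held 2 peaks within the gene or 5 kb of it. The stronger, 601.5 (5083622 to 5083893), lay inside the gene's span, at -749 bp from an internal TSS of CG32767, and above 98.6% of the list, with a signal of 388.2 in replicate 1 and 219.1 in replicate 2. The other, 89.3 (5085844 to 5086233), lay 280 bp downstream of the TSS of the neighbouring CG15465. The transgene adds a copy of the tagged gene, and the peak lists alone do not separate signal from the added copy and the native locus.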

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

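Some peaks lay outside the 6 chromosome arms and entered no test that needs the annotation. The list of replicate 1 held 12 such peaks, all on scaffolds assigned to the X, and the other series-level list held 16, against 0 in the list of replicate 2 and 2 in the conservative list. The counts of 12 and 16 are listed because they are above 3, and the difference between the lists was not tested.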

How the results depend on the processing

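The share of summits at promoters stayed above its random share, at the smallest p the placements can give, under all 9 alternatives, from 39.6% with a window of 250 bp to 62.1% with 1000 bp, and 5 annotation classes differed from random under each of the 5 other lists. The alternative that kept the strongest of summits within 1000 bp was chosen after seeing the data. The cause of the changes below was not tested.

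The share of replicate 1 peaks found in replicate 2 was 48.1% with a reciprocal overlap of 50%, 51.7% with summits within 100 bp and 61.0% in the upper 50% of the lists by signal. The Spearman correlation was 0.669 with summits within 100 bp and 0.565 over main-list peaks, and the Pearson correlation 0.721 and 0.712. With reciprocal overlap of 50%, 89.6% of conservative peaks were in the other series-level list. The density ratio of X to autosomes ran from 0.837 to 1.01 when either replicate was left out, and the log2 difference of promoter and other summits from 0.030 to 0.22. Within 50 kb of CG32767 there were 5 peaks.

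Against 12 lists called, 7 were called among genes with a candidate peak and 4 without genes that share a promoter, where fewer genes were tested. Odds ratios of snoRNA genes turned to 1.08 with a window of 1000 bp and 1.60 with summits in the gene or 2 kb upstream, where ecdysone pathway genes had 2.95. Histone genes had 1.45 among genes with a candidate peak, with 1 gene left, and mitochondrial ribosomal protein genes 0.417 without genes that share a promoter, with 13 left. Of 330 single list values under alternatives, 281 kept their call or lack of one, 28 lost a call, 16 gained one and 5 turned with a call on at least 1 side. Turns between values without a call are among those kept, here and for motifs.

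Against 13 motifs called, 21 were called with shuffled windows as background, which shared 6 calls with the main test, and 6 at promoter summits against promoters without a peak. With shuffled windows the odds ratios turned, with a call on at least 1 side, for the Zelda site (2.10), the E-box CAGCTG (2.19), the TATA box (0.836), GATA (0.845), homeodomain (0.800) and Mad sites (1.64), the Sp/KLF box (1.62) and the CACCC box (1.79). Against promoters without a peak they turned for core promoter motif 1 (0.879), the TATA box (0.903), GATA sites (0.946) and the Sp/KLF box (1.07). Without either replicate in turn, GAGAGAG ran from 0.583 to 1.41, CACACACA from 0.610 to 1.56 and GTGTGTG from 0.652 to 1.52. With shuffled windows, in which repeats are broken up, they were 4.13, 4.77 and 3.36. Of 252 single motif values, 180 kept their call or lack of one, 27 lost a call, 30 gained one and 15 turned with a call on at least 1 side. The E-box CAGGTG was lower under all 9 alternatives. Unknown depth limits how far the shorter lists can be read as absence of binding.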

Other observations

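The comparisons of peaks of 1 replicate alone, of genes with divergent neighbours and of transposable elements, and the tests in equally long lists, were chosen after results had been seen, as were the patterns to which the other tests below were applied. Genes with a divergent neighbour had a summit near a TSS more often. Of 5052 protein-coding genes with a divergent protein-coding neighbour within 1000 bp, 1186 (23.5%) had a main-list summit within 500 bp of a TSS, against 779 of 8893 others (8.76%, odds ratio 3.20, Fisher's exact p = 3.543e-122). With a window of 250 bp the shares were 19.7% and 6.44%, but with either window 1 summit between close neighbours counts for both genes, and how much of the difference this makes was not tested. An example is CenG1A with mRpS23. Annotated transposable elements held 4 summits (0.113%) against 5.83% in random placements (permutation p = 0.002), but of the 120150 candidates in the ranked list 746 (0.621%) lay in them, so the comparison with random positions says little about binding there. The genes with the most summits in their span were kirre (13 in 394.1 kb), CG1677 (12 in 124.7 kb), sbb (11 in 79.1 kb) and CG14434 (10 in 15.3 kb), the last the densest at 0.654 per kb.

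Peaks in the list of 1 replicate alone differed in sequence, though many were not absent from the combined data. The conservative list, made from both replicates, overlapped 756 of 1234 such peaks of replicate 1 (61.3%) and 489 of 931 of replicate 2 (52.5%). The 1234 include peaks outside the arms, which the counts below leave out. Those of replicate 1 alone were close to the shared ones in base composition, with 33.8% G and C (1222 peaks) against 34.0% (1653 shared peaks), while those of replicate 2 alone had 44.0% (931 peaks). In the share at promoters it was replicate 2 alone that was close, with 54.7% of its peaks there against 55.5% of shared peaks and 43.0% of those of replicate 1 alone. By chromosome it was not. Replicate 2 alone had 27 of its 931 peaks on the fourth and 100 on the X. The 1653 shared peaks had 6 and 291, and the 1222 of replicate 1 alone had 1 and 222. The CA repeat CACACACA was in 9.34% of peaks of replicate 2 alone, 1.55% of those of replicate 1 alone and 2.78% of shared ones (replicate 2 against 1, odds ratio 6.53, adjusted Fisher's exact p = 7.319e-16). GTGTGTG was in 12.1% against 2.78% and GAGAGAG in 6.23% against 1.39% (adjusted Fisher's exact p = 4.426e-16 and 1.361e-08). A word search on replicate 2 alone gave ATACACA first, in 13.8% of held-out windows against 3.12% of flanks (64 of 465 windows, adjusted Fisher's exact p = 6.517e-12), then words such as GTGTGTA and AGATACA, and no word of A and T alone. Of 436 protein-coding genes with a promoter peak of replicate 2 alone, 15 belonged to the 11 patterning and tissue lists, among them Scr, ci, brk, hry, pnr and rib, against 3 of 642 for replicate 1 alone (E(spl)mdelta-HLH, Tm1 and piwi, odds ratio 7.59, Fisher's exact p = 0.000303). These lists hold 168 of the 13945 protein-coding genes, and their share at shared peaks is not given here. Some of the 15 were not particular to replicate 2. Abd-B, among them, had another promoter peak in both replicate lists, and ci, pnr and rib had main-list summits.

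On the fourth chromosome replicate 1 had 7 peaks and replicate 2 had 35, and on the X they had 513 and 396, while among all candidates they had 95 and 294 on the fourth (odds ratio 3.48, Fisher's exact p = 3.649e-30) and on the X a share of 16.3% and 17.2%, the other way (odds ratio 1.07, Fisher's exact p = 4.199e-07). In lists of 2624 peaks each, the CA repeat (Fisher's exact p = 1.863e-17), the fourth chromosome (Fisher's exact p = 4.504e-06) and the X (Fisher's exact p = 0.00115) still differed. The differences were therefore present at equal length, but the check was a weak one. The trim took few peaks, from replicate 1 alone, and left it 6 on the fourth and 485 on the X. It could hardly have removed the differences, and it does not bear on depth or thresholds. A first version with candidates of the ranked lists gave Fisher's exact p = 0.000791 and 0.00191 for the chromosomes. A library of replicate 1 that favoured AT-rich fragments was argued against for the fourth chromosome. For the CA repeat it was argued against as the whole source alone. Within 10 classes of G and C content, the fourth chromosome's odds ratio of replicate 2 to 1 went from 5.54 to 6.01 (95% interval 2.61 to 13.8). That of the CA repeat went from 6.53 to 3.17 (1.87 to 5.37), so part of its difference went with composition. For the X the odds ratio went from 0.818 to 0.874 (0.755 to 1.01), so part of the difference remained. That interval included 1, which by the rule written before its value was seen goes with such a library. The explanation stays open for the X and for part of the CA repeat difference. The weakest candidates of the replicates, given below, cannot decide it. A signal shifted over the whole of chromosome 4 in replicate 2 cannot be told apart, since 29 of its 51 candidate sites seen in both replicates (56.9%, 95% exact interval 42.2 to 70.7) lay above the median ratio of the other arms, too few to decide, and the larger number of candidates there goes with such a shift without showing one. It stays open whether replicate 2 may hold a second class of sites, from embryos of another age mix or through another protein in an unspecific or mixed-in precipitate, which the peak lists did not allow to be tested.

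The AT-rich summits were weighed against base composition in general. Promoters of genes without a peak, at the same distances from their TSS, had more G and C than promoter summits, by a difference of -4.20 percentage points (95% bootstrap interval -4.86 to -3.54, summits minus promoters without a peak), and summits away from promoters were lower than their flanks as well (-4.81, -5.40 to -4.20). Libraries rich in AT fragments everywhere were weighed with the 5000 weakest candidates. These were richer in G and C than random positions by 2.89 points (2.49 to 3.29). The larger dip in replicate 1 was not matched in its weakest candidates, which differed from those of replicate 2 by 0.133 points (-0.259 to 0.520). But these candidates have the lowest signal, and G and C content rose from the strongest to the weakest peaks. A bias that raised signal at AT-rich sequence could leave them rich in G and C as well, so they cannot decide. Such a bias, in both libraries or more in replicate 1, stays open, and whether the tagged protein itself prefers AT-rich sequence was not tested.

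The lists with frequent promoter summits were weighed against the amount of promoter sequence per gene and against divergent neighbours. Random lists matched on promoter length had summits at 15.7% of genes for segment polarity genes, 22.6% for zygotic genome activators, 14.8% for insulator genes, 13.4% for cytoplasmic and 10.8% for mitochondrial ribosomal protein genes, each below the observed share (permutation p from 0.0002, the smallest that 10000 lists can give, to 0.0368), and 16.2% for Polycomb and Trithorax genes, where the matter cannot be told apart (permutation p = 0.0694). Lists matched on divergent neighbours as well had 12.5%, 23.3%, 16.6% and 17.0% for the first 4 lists (permutation p from 0.0002 to 0.0082), but 17.2% for mitochondrial ribosomal protein genes (permutation p = 0.0706), of which 79.5% have a divergent neighbour, and 18.1% for Polycomb and Trithorax genes (permutation p = 0.120), so for these lists this explanation cannot be told apart from a preference for the group. Open chromatin at highly used promoters, which could draw peaks for many tagged proteins, was not tested.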
